A study of Rattus norvegicus with 36 samples.

How the data were processed

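DNA methylation was profiled in germ cells of male rats at 9 stages with 4 samples each, 36 samples in all, which were grouped by the stage in their titles. Per the labels, germ cells were isolated by fluorescence-activated sorting of cells with germ-cell-specific green fluorescent protein, and spermatozoa were extracted with a kit of their own. Libraries were made with a capture panel for the rat methylome, so that only captured regions carry values. The labels do not say whether the samples of a stage came from separate animals, and the p-values below measure spread between regions or CpGs and not spread between animals.

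Per the submitters' processing notes, Bowtie2 and Bismark 0.19.0 were used. Per the labels, levels were extracted at each mapped locus of each sample, the genome was divided into segments of at least 50 bp and differentially methylated regions were then searched. Some listed regions are shorter than this. The genome build, the coverage minimum and the way the samples of a stage were combined are not given in the sources used here. Each of the 7 deposited region lists gives the methylation level of a region in both stages as a fraction between 0 and 1, per the file headers a mean over the CpGs of the group, and it is printed here as a percentage. The authors also deposited the difference of the 2 means, the number of CpGs, the length, and for each region a p-value of a two-sample test and an adjusted p-value, per the file headers. No depth per sample or per region was used here, so no interval on a single level can be given, and the depth behind the levels is unknown.

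The authors' adjusted p-values were read back against their p-values. The number of regions in each adjustment is not given in the sources used here and was only inferred in this way. The inferred numbers were 282 from GD16 to GD18, 44483 from GD18 to GD20 and 46674 from GD20 to PND5. For the spermatid lists in order they were 4856, 7695, 5831 and 2747. In the fetal and neonatal lists these numbers are close to the lengths of the lists. In the spermatid lists they exceed the 3722, 5612, 3023 and 1691 listed regions but stay far below the 60036 distinct regions of all lists. The lists also have a smallest difference, so regions that passed on p alone may be missing from them. The inferred numbers may then be too low. These comparisons therefore do not tell how many regions were tested, which is unknown. All listed regions had an adjusted p of at most 0.05. Regions that did not pass were not used here, so counts adjusted over the list alone cannot be given for the gene lists, and an expected overlap of independent lists was not computed.

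Differences were expressed as the later minus the earlier stage, and the sign was checked against the 2 levels of each region. Shares of gains and of X-linked regions carry Wilson 95% intervals, which cover counting error only and treat regions as independent, although neighbouring regions are not. Regions of different lists were matched by an overlap of at least 1 bp, and levels at other stages were taken from the lists that hold the same region, so that a level at a stage exists only for listed regions. For consecutive lists, scatter of independent stage means was simulated to find the share of opposite directions, and the net difference, that a shared stage gives without any change. Regions shared by fetal and spermatid lists were compared with the other spermatid regions over all levels and within bands of the earlier level. The net change over 2 steps was called small within 10 points. All Fisher exact tests and permutation tests were two-sided, with 100000 resamples for the latter, and the families of list tests, of 40 tests of gene parts, of 10 tests of X linkage and of directions in shared regions were adjusted by the Benjamini-Hochberg method; other p-values are unadjusted.

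Gene parts and gene symbols were taken from the authors' deposited annotation of the regions. These sets covered 84.9%, 86.1%, 84.3% and 74.9% of the regions of the spermatid lists in order. Tests of gene parts in spermatids therefore run on regions that the authors had chosen mostly by their course of methylation. Counts of genes and of list members in spermatids leave out the remaining regions and may miss members there. The table of gene names that was used to match older symbols and gene numbers is that of assembly GRCr8, which served for names only. Of 29951 regions annotated to a gene, 28189 (94.1%) had a symbol. Of 6811 gene numbers in the tables of gene ontology terms, 6805 were matched. Because no genome of the build was used, the promoter definition and the CpG island test of the design were replaced by the authors' annotation and by CpGs per 100 bp of a region, and random gene lists matched on gene length and CpG number were replaced by the Fisher exact test stated for that case.

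The comparisons, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The 13 gene lists were imprinted genes, germline genes silenced in somatic cells with the piRNA pathway, DNA methylation machinery, histone-to-protamine transition and spermatid genes, stem cell, progenitor and pluripotency genes, Hox and other developmental transcription factors, synapse and axon guidance genes, Wnt and TGF-beta pathway genes, histone-modifying and chromatin-remodelling enzymes, markers of Sertoli cells, of Leydig and peritubular cells and of blood and endothelium, and olfactory and vomeronasal receptors. Each was tested in each of the 7 comparisons, 91 tests, against the 9453 genes named in any deposited table, of which 8134 came from the annotated regions and the rest from the term tables. Members of a list outside these genes were not counted. Directions within a list were tested too, and no such test passed adjustment.

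Genes were named by rule: in each comparison the 10 largest gains and the 10 largest losses, with the largest difference of each gene, up to 4 members of each gene list, up to 5 genes of each group or cluster, and all genes of the set of reprogrammed sites up to 30. A selection of these is printed, and not every gene that the rule gives; an item of the reprogrammed set is not reported here. The ranking of genes in the clusters was limited to the spermatid comparisons, and that in the gain groups to the comparisons from GD18 to PND5, after a ranking over all comparisons had been seen. The minimum of 40% for drawing a stage in the plots of groups and clusters was likewise set after an earlier plot had been seen. Term tables are reported as the authors gave them.

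Overlaps and list tests were tested on simulated data for the comparison from R1-8 to R9-12. Among 5000 simulated regions, 100% of the planted overlaps and 100% of the planted opposite directions were recovered. These regions held no noise and no values of the real lists, so this checked only the matching of regions. With 9000 genes, a list of 70 members of which 35% held a region, against 10% of genes, was called in 97.5% of 200 draws, and neutral lists in 0.117% of 12000 tests. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

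The alternatives tried were an adjusted p under 0.001, a difference of at least 30 points, merging of regions of the same direction within 500 bp, weighting by length, autosomes only, regions of at least 200 bp, an overlap of 50% of both regions or a distance within 500 bp, all 23154 annotated protein-coding genes as the comparison set, and an adjusted p under 0.01 for terms. Added after the data were seen were an adjustment over the distinct regions of all 7 lists and list tests with regions as the unit.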

Results

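DNA methylation was measured in male germ cells of Sprague-Dawley rats that carry a green fluorescent protein made only in germ cells, so that these cells could be sorted from the gonad. Bisulfite sequencing of captured genomic regions covered 9 stages with 4 samples each, 36 samples in all. The stages were gonocytes labelled GD16, GD18 and GD20, spermatogonia labelled PND5, spermatids of the ranges R1-8, R9-12, R13-14 and R15-17, and spermatozoa. The authors compared neighbouring stages in 7 lists of differentially methylated regions, and PND5 spermatogonia were not set against R1-8 spermatids in any of the lists used here. Each listed region carries the authors' mean methylation level in the earlier and in the later stage. The values hold no replicate measurements, so no level below has an SD or n, and the read depth behind the levels is unknown. A gene below is named with the region of it that was listed, at the coordinates of the region lists, whose genome build is not given in the sources used here.

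The number and the direction of the listed regions changed with the stage of development. The lists held 282 regions between GD16 and GD18, 44477 between GD18 and GD20 and 46665 between GD20 and PND5. The spermatid lists were shorter, with 3722 regions from R1-8 to R9-12, 5612 from R9-12 to R13-14, 3023 from R13-14 to R15-17 and 1691 from R15-17 to spermatozoa. Per the authors' deposited table, the smallest listed difference was 30 percentage points in the fetal and neonatal lists and 10 points in the spermatid lists, so that the numbers of the 2 kinds of list cannot be set against each other directly. At 30 points or more the spermatid lists held 82, 153, 130 and 55 regions in the same order.

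**Figure D1:**
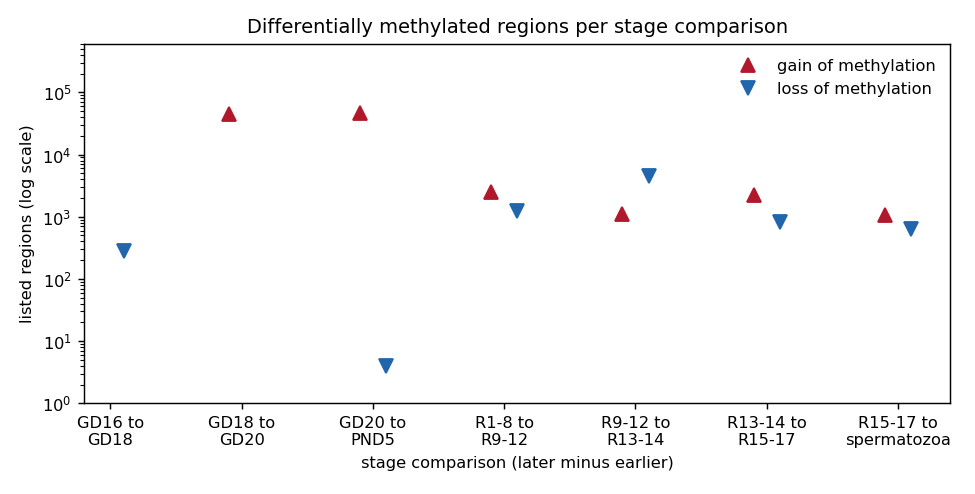
Number of listed regions on a log axis for each of the 7 comparisons of neighbouring stages, with a triangle pointing up for gains of methylation and down for losses; counts of 0 are not drawn. All 282 regions of the first comparison were losses, all 44477 of the second were gains, and losses outnumbered gains in the spermatids only from R9-12 to R13-14, with 4504 losses and 1108 gains.

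Gonocytes lost methylation between GD16 and GD18 at the promoter of Cfi, which encodes complement factor I, at an exon of Yeats2, a subunit of a histone acetyltransferase complex, and at an intron of Vav2, a signalling gene. The Cfi promoter (chromosome 2, 235264237 to 235264441) fell from 48.3% to 1.1%, exon 5 of Yeats2 (chromosome 11, 84575543 to 84575663) from 43.8% to 2.4%, and intron 3 of Vav2 (chromosome 3, 5881671 to 5882156) from 49.7% to 9.2%. Intron 5 of Etv5 (chromosome 11, 82201402 to 82201866), a transcription factor needed for self-renewal of spermatogonial stem cells, fell from 35.7% to 3.9%. Introns of Akap6, Slc6a5 and Mbnl1, which encode an anchor of protein kinase A, a glycine transporter and a splicing regulator, started at 40.6%, 40.8% and 41.7% and ended at 1.5%, 2.3% and 3.9%. All 282 regions fell, from a median of 35.8% to a median of 2.8%, and 0 gains among 282 regions allow a share of gains of up to 1.34% (Wilson 95% interval, counting error only).

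The regions that lost methylation by GD18 lay mostly between genes: 180 of the 282 regions (63.8%) were intergenic and 68 (24.1%) intronic, and 7 lay in promoters. Of the 68 synapse and axon guidance genes that could be found, 3 held a loss: Dlgap2, which encodes a scaffold of the postsynaptic density, Ephb1, an ephrin receptor, and Robo1, a Slit receptor. The loss at intron 1 of Dlgap2 (chromosome 16, 80575071 to 80575422) was from 36.9% to 3%, that at intron 3 of Robo1 (chromosome 11, 9800211 to 9800308) from 31.3% to 1.2%. Among the markers of blood and endothelium, 1 of 9 genes was listed, the endothelial receptor Tie1, whose intron 14 fell from 41.7% to 1.8%. Etv5 was the only listed member, of 28, of the stem cell and pluripotency list, and the remaining 10 gene lists held no listed member. None of the 13 lists passed the Fisher exact test at this step, the synapse list with an adjusted p of 0.295, although over all annotated genes that list had an odds ratio of 11.3 and an adjusted p of 0.0167. The authors' deposited table of gene ontology terms names 4 terms for these genes, led by negative regulation of locomotion with 12 of 94 genes and an adjusted p of 0.00289.

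Between GD18 and GD20 gonocytes gained methylation across the genome, and the largest gains took single gene regions from nearly unmethylated to nearly fully methylated. Intron 6 of Gmnn (chromosome 17, 42309258 to 42309356), whose product geminin holds back the licensing of DNA replication, rose from 3.7% to 93.3%. Intron 4 of Xab2 (chromosome 12, 2164962 to 2165111), a factor of transcription-coupled repair, rose from 4.8% to 94.3%, and intron 1 of the neurotrophin gene Ntf3 (chromosome 4, 158676413 to 158676536) from 5.6% to 94.1%. Intron 1 of Myo5b, a myosin of vesicle transport, rose from 3.8% to 92.7%, and exon 6 of Rnps1, an RNA-binding protein of the splicing machinery, from 8.6% to 94.5%. All 44477 regions gained, from a median of 5.2% to a median of 54.9%, by a median of 49.5 points (interquartile range 41.8 to 57).

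Genes of every fixed list took part in this gain. Members are counted among the named genes only, of which 72.7% held a gain. Of the 18 imprinted genes, 11 held gains, among them Igf2r, the receptor that clears insulin-like growth factor 2, where intron 37 rose from 15.6% to 87.4%, and Rasgrf1, where intron 31 rose from 7.2% to 78.2%. Gains were listed in 14 of 22 germline genes, with an intron of the piRNA factor Tdrd1 rising from 9.2% to 86.4% and Piwil1, a piRNA-binding protein, from 3.8% to 70.6%. Of the DNA methylation machinery, 10 of 17 genes gained, and intron 2 of the de novo methyltransferase gene Dnmt3a (chromosome 6, 28328119 to 28328498) rose from 9.6% to 77.3%. The spermatid list gained at 21 of 30 genes and the stem cell list at 20 of 28, where Gfra1, a receptor subunit for the niche factor GDNF, rose from 7.9% to 83.8% and Zbtb16, a repressor of stem cell differentiation, from 7.7% to 77.4%. Gains were found in 50 of 68 synapse genes, such as the glutamate receptor gene Grin2a from 8.3% to 91.2%, in 45 of 63 Wnt and TGF-beta genes, such as Wnt3 from 9% to 86%, and in 26 of 38 chromatin enzymes, such as Dot1l from 15.5% to 89.4%. Markers of other testis cells gained too: 4 of 11 Sertoli cell markers, 4 of 6 Leydig and peritubular markers and 8 of 9 blood and endothelial markers. Among these, Sox9, which directs Sertoli cell fate, rose from 6.2% to 49%, the smooth muscle actin gene Acta2 from 4.3% to 65% and the endothelial adhesion gene Pecam1 from 7.3% to 71.1%. Olfactory and vomeronasal receptor genes gained at 44 of 64 named members. Over all annotated genes, these receptors were listed far less often than other genes, at 44 of 1380 members (3.19% against 29.7%, odds ratio 0.0722, Fisher exact test, adjusted p = 5.31e-149). How many of them the capture panel covers is not known here.

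Hox and other developmental transcription factors were listed less often, with gains at 19 of 67 genes (28.4%) against 72.7% of all genes named in the tables. Sertoli cell markers, at 36.4%, did not pass adjustment by genes (Fisher exact test, adjusted p = 0.165). With regions as the unit, an alternative chosen after the data were seen, listed gains were less frequent in Sertoli cell markers (33.3% of 12 regions against 81.7%, Fisher exact test, adjusted p = 0.0140) and in olfactory and vomeronasal receptors (64.8% of 71 regions, adjusted p = 0.0188). The regions counted are only those that the authors had listed or grouped at some step, so 81.7% is not a share of all measured regions. A lower share means listing at another step: 9 of the 12 Sertoli regions gained from GD20 to PND5. For the developmental transcription factors the odds ratio was 0.146 by genes (two-sided Fisher exact test, adjusted p = 4.26e-12 over 91 tests of lists) but 0.442 with regions as the unit (66.4% of 140 regions against 81.8%, Fisher exact test, adjusted p = 0.00132). The members that did gain included Sox5 from 7.5% to 82.4%, Pax2 from 8.8% to 72.4% and Meis1 from 4.9% to 68.9%. The result depends on the set of genes compared: over all annotated genes the odds ratio was 0.592 with an adjusted p of 0.148. The set of named genes includes genes from the authors' deposited table of terms for stable segments, whose biological processes are led by morphogenesis of an epithelium with 421 genes and an adjusted p of 1.11e-04 and include pattern specification process with an adjusted p of 1.13e-04.

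From GD20 gonocytes to PND5 spermatogonia methylation rose further, to nearly complete levels. Intron 1 of Arsj (chromosome 2, 230420038 to 230420157), an arylsulfatase gene, rose from 5.3% to 100%, the promoter of Angpt4 (chromosome 3, 147421616 to 147421686), an angiopoietin gene, from 4.7% to 97.5%, and exon 3 of Cmtm8 (chromosome 8, 122849777 to 122849870) from 7.7% to 98.8%. The 3' UTR of Txnip, which encodes an inhibitor of thioredoxin, rose from 6.2% to 96.5%. The 3' UTR of Nanos2 (chromosome 1, 79894895 to 79895464), an RNA-binding protein of male germ cell fate, rose from 20.4% to 95.1%, and exon 2 of Prdm1, a determinant of primordial germ cells, from 9.4% to 85.1%. Of 46665 regions 46661 gained, from a median of 48.3% to a median of 96.5% and by a median of 45.6 points (interquartile range 38.4 to 54.5).

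Only 4 regions of this list lost methylation, and they were chosen for naming after their values were seen. Intron 1 of Maff, a small Maf transcription factor gene (chromosome 7, 120582948 to 120583129), fell from 36.1% to 0.7%. An intron of Sdc3, a cell surface proteoglycan gene (chromosome 5, 148932429 to 148932716), fell from 66.5% to 34.8% after a GD18 level of 3.6%. The other two lay between genes, on chromosome 3 at 59776897 to 59776993, from 35.1% to 1.6%, and on chromosome 10 at 49952863 to 49953152, from 38.7% to 5.4%.

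Listed members were again frequent in most gene groups at this step. Gains were held by 11 of 18 imprinted genes, with Rasgrf1 rising from 31.7% to 99.6%, and by 15 of 22 germline genes, with exon 1 of Tex15, a factor of piRNA-directed silencing, rising from 24.2% to 94.2%. The counts were 12 of 17 for the methylation machinery, 21 of 30 for spermatid genes, 22 of 28 for stem cell genes, 53 of 68 for synapse genes, 52 of 63 for Wnt and TGF-beta genes and 30 of 38 for chromatin enzymes. Among the markers of other cells 7 of 11 Sertoli, 4 of 6 Leydig and 8 of 9 blood genes held gains, with the follitropin receptor gene Fshr from 21.2% to 82.4% and the leukocyte gene Ptprc from 38.1% to 92.8%. Olfactory receptors were listed at 51 of 64 named genes, but at only 51 of 1380 annotated ones (3.70% against 31.9%, odds ratio 0.0756, Fisher exact test, adjusted p = 6.21e-159). Developmental transcription factors were again listed less often, at 25 of 67 genes (37.3% against 78.1%, odds ratio 0.164, Fisher exact test, adjusted p = 2.77e-11). This call was lost over all annotated genes, with an odds ratio of 0.762 and an adjusted p of 0.587, and with regions instead of genes as the unit, with 0.915 and an adjusted p of 1, an alternative chosen after the data were seen.

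The authors sorted the regions that gained methylation into an early group of 8083 regions, a continuous group of 36401 and a late group of 10275. These groups were selected on the same levels and are no independent evidence of the course of gain. The early group rose from a median of 7% at GD18 to 71.1% at GD20, the continuous group from 5% through 52.2% to 97.1% at PND5, and the late group from 23.5% at GD20 to 85.9% at PND5. Genes of the continuous group included Cfap206, a gene of the ciliary and sperm flagellar axoneme, which rose from 32.6% to 100% between GD20 and PND5, and Ehmt2, a histone H3 lysine 9 methyltransferase, which rose from 1.8% to 67.6% between GD18 and GD20. Genic regions made up 60.2% of the early group, 53.9% of the continuous group and 40.2% of the late group, and promoters made up 2.98%, 3.41% and 7.48% of these genic regions. CpG density rose in the same order, with medians of 1.83, 2.05 and 2.43 CpGs per 100 bp. In the authors' deposited table of terms the early group was led by cell leading edge with 128 genes and an adjusted p of 5.57e-07. There the continuous group was led by cell adhesion molecule binding at 1.62e-07, and the late group by apical part of cell at 4.88e-06 in the authors' deposited table, where synapse organization stood at 1.01e-05.

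**Figure D2:**
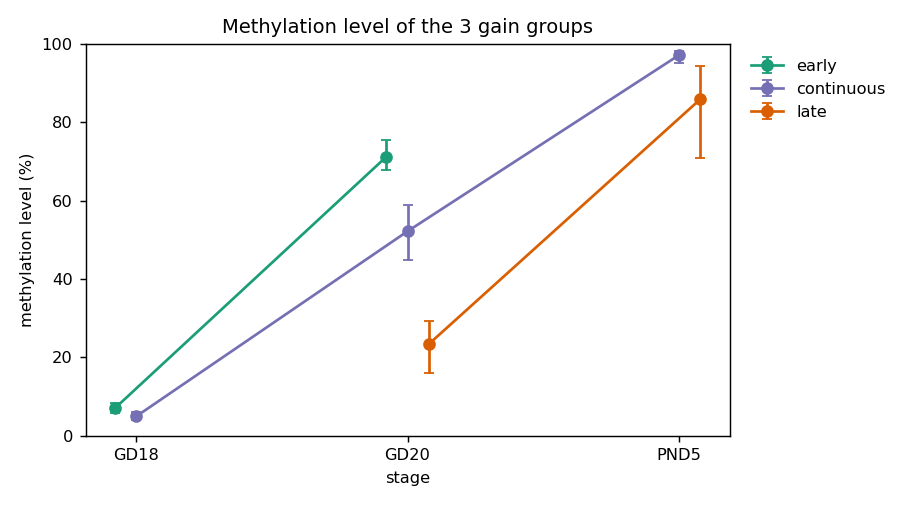
Median of the authors' mean methylation level in percent at each stage, for the regions of the early, continuous and late gain groups, over the regions with a level and with the interquartile range as error bars, drawn where at least 40% of a group's regions have a level. At GD20 the medians were 71.1% for the early, 52.2% for the continuous and 23.5% for the late group.

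From R1-8 to R9-12 spermatids methylation changed in both directions, and most regions gained. Intron 3 of Spag16 (chromosome 9, 77360437 to 77360649), a gene of the sperm tail axoneme, rose from 2.4% to 54.7%. Intron 2 of Cldn11 (chromosome 2, 115828705 to 115828741), which encodes a tight junction protein and stands in the list of Sertoli cell markers, rose from 1.9% to 40.6%, and intron 3 of Robo1 from 2.2% to 39%. The promoter of Smarca5 (chromosome 19, 30936641 to 30936661), a chromatin-remodelling ATPase, fell from 41.8% to 2.9%, exon 1 of the Wnt receptor gene Fzd1 (chromosome 4, 26471417 to 26471629) from 47.2% to 9.2%, and intron 8 of the cell polarity gene Crb1 (chromosome 13, 56314125 to 56314256) from 76.9% to 37.9%. Gains numbered 2486 and losses 1236, a gain share of 66.8% (Wilson 95% interval 65.3% to 68.3%, counting error only). Gains started low, at a median of 9.6%, and reached 25.2%, and losses started high, at 93.7%, and reached 79.2%.

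Several germline genes with low levels at R1-8 gained methylation at R9-12. The promoter of Stk31 (chromosome 4, 79055485 to 79055622), a kinase gene of the germ line, rose from 0.8% to 21.1%, the promoter of Asz1 (chromosome 4, 45414205 to 45414713), a piRNA pathway gene, from 5.5% to 19%, and intron 1 of Dazl (chromosome 9, 12634197 to 12634335), an RNA-binding protein of germ cells, from 4.3% to 17.8%. With Ddx25, which fell from 97.3% to 86.2%, 4 of 22 germline genes were listed (18.2% against 9.88% of all named genes, Fisher exact test, adjusted p = 0.970). None of the lists in this paragraph passed adjustment. Low regions of this comparison mostly gained: leaving out those erased by GD18, 97.4% of 1792 regions that started under 20% did so. Of the spermatid genes 4 of 30 were listed, with Klhl10, a ubiquitin ligase adaptor of spermatids, rising from 4.8% to 27.4% and the histone variant gene H3f4 from 6% to 22.4%. Listed were also 2 of 17 genes of the methylation machinery, Dppa3 from 9.3% to 23.6% and Kdm1b from 6.9% to 22.9%, and 3 of 28 stem cell genes, with Tfap2c falling from 97.4% to 80.3%. Of the Sertoli cell markers 2 of 11 were listed: Cldn11, which rose, and the inhibin gene Inha, whose promoter fell from 91.9% to 76.7%. The counts were 6 of 67 for developmental transcription factors, 8 of 63 for Wnt and TGF-beta genes, 6 of 38 for chromatin enzymes and 5 of 64 for olfactory receptors. The imprinted, Leydig and blood lists had no listed member among the 84.9% of regions that carried an annotation.

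Synapse and axon guidance genes were listed more often than other genes at this step, with 19 of 68 genes (27.9%) against 9.88% of all named genes. They held 20 gains, such as the adhesion gene Cdh13 from 6.6% to 31.8% and the neuroligin gene Nlgn2 from 17.6% to 37.4%, and 11 losses. The odds ratio was 3.59 (Fisher exact test, adjusted p = 3.69e-04). With regions as the unit it was 1.21 and its adjusted p was 0.780, an alternative chosen after the data were seen. Gains and losses lay in different parts of genes: exons held 8.96% of gains against 4.66% of losses (Fisher exact test, adjusted p = 4.98e-05 over 40 tests of gene parts) and introns 18.9% against 34.8% (adjusted p = 1.73e-20), among the 84.9% of regions that carried an annotation. Gains had a higher median CpG density, 3.44 against 2.58 CpGs per 100 bp for losses.

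From R9-12 to R13-14 losses prevailed. Exon 3 of Lzts2 (chromosome 1, 264774294 to 264774397), a gene named as a tumour suppressor, fell from 96.7% to 47.6%, and the promoter of Mfhas1 fell from 45.8% to 11.7%. Spag16, Cldn11 and Klhl10, which had risen at the preceding step, fell back to 8.6%, 1.8% and 4.9%. The promoter of Slc38a2 (chromosome 7, 138101084 to 138101113), a transporter of neutral amino acids, rose from 2.6% to 48.4% and was at 0% again at R15-17. The promoter of Hoxc12 (chromosome 7, 144547002 to 144547140) rose from 0.9% to 23.9% and likewise fell back, to 1.8%. Losses numbered 4504 and gains 1108, a gain share of 19.7% (Wilson 95% interval 18.7% to 20.8%), with losses from a median of 30.4% to 12.9% and gains from 77.5% to 93%.

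In the germline list 7 of 22 genes were listed, with Asz1 falling to 2.1%, Dazl to 3.7% and exon 1 of Tdrd6, a gene of the chromatoid body, from 26.8% to 5.9%. Of the spermatid genes 10 of 30 were listed, among them Gopc, a Golgi protein needed to build the acrosome, which fell from 98.2% to 83.2%. Neither list passed adjustment, with adjusted p of 0.553 and 0.205 (Fisher exact tests). Over all annotated genes the spermatid list passed, with an odds ratio of 3.25 and an adjusted p of 0.0143 (Fisher exact test), as did developmental transcription factors with 2.37 and 0.0412. Of the methylation machinery 3 of 17 genes were listed, and the promoter of Dnmt3l (chromosome 20, 11359610 to 11359760), the cofactor of the de novo methyltransferases, fell from 15.2% to 2.7%. Synapse genes were listed at 27 of 68 members (39.7% against 15.4%, odds ratio 3.66, Fisher exact test, adjusted p = 2.37e-05), with 39 losses and 5 gains. The losses included another site in intron 3 of Robo1 from 73.9% to 43.7% and Epha4, an ephrin receptor, from 26.6% to 4.8%, and a gain in intron 5 of the synapsin gene Syn3 went from 46.2% to 85.2%. With regions as the unit the odds ratio was 1.04 and the adjusted p 1. The counts of the other lists were 1 of 18 imprinted genes, 4 of 28 stem cell genes, 13 of 67 developmental transcription factors, 7 of 63 Wnt and TGF-beta genes, 5 of 38 chromatin enzymes, 2 of 11 Sertoli markers, 0 of 6 Leydig markers, 1 of 9 blood markers and 5 of 64 olfactory receptors. Exons held 4.87% of gains against 9.19% of losses (Fisher exact test, adjusted p = 4.88e-05) and introns 32.9% against 23.6% (adjusted p = 8.08e-08).

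From R13-14 to R15-17 gains prevailed again. Lzts2 returned to 95.5%, and intron 1 of Ttc23 (chromosome 1, 128614636 to 128614737), a gene of the primary cilium, rose from 1% to 50.9%. The promoter of Prm3 (chromosome 10, 4950550 to 4951145), which lies in the protamine gene cluster, rose from 72.6% to 91.3%, and the promoter of Dnmt3a (chromosome 6, 28234868 to 28235303) from 7.1% to 23.9%. Intron 1 of the receptor kinase gene Ros1 (chromosome 20, 33321732 to 33321919) fell from 92% to 45.9%, and the promoter of Trim28 (chromosome 1, 65550974 to 65550996), a corepressor that guards imprints, from 39.5% to 13.5%. Gains numbered 2205 and losses 818, a gain share of 72.9% (Wilson 95% interval 71.3% to 74.5%), with gains from a median of 80% to 95.5% and losses from 47.3% to 24.7%. With an adjusted p under 0.001 the list held 277 regions, of which 57.0% were gains, against 68.9% gains in the list to spermatozoa.

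Of the synapse genes 21 of 68 were listed (30.9% against 9.76%, odds ratio 4.20, Fisher exact test, adjusted p = 2.37e-05), with 26 gains and 7 losses. The neurotrophin receptor gene Ntrk2 rose from 66.3% to 89.8% and Dlgap2 from 78.9% to 99%. With regions as the unit the odds ratio was 1.39 and the adjusted p 0.544, and at 30 points or more no member was listed. The spermatid list held 6 of 30 members, with the remodeller gene Chd5 rising from 79.4% to 94.4%, the methylation machinery 3 of 17 and the imprinted list 1 of 18, where exon 23 of Rasgrf1 (chromosome 8, 97359651 to 97359874) rose from 62.7% to 87.5%. The counts were 2 of 28 for stem cell genes, 5 of 67 for developmental transcription factors, 6 of 63 for Wnt and TGF-beta genes, 4 of 38 for chromatin enzymes, 1 of 6 for Leydig markers, 1 of 9 for blood markers and 2 of 64 for olfactory receptors. The germline and Sertoli lists had none among the 84.3% of regions that carried an annotation. Introns held 32.9% of gains against 20.3% of losses (Fisher exact test, adjusted p = 2.85e-08) and promoters 2.72% against 5.5% (adjusted p = 0.00779).

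Between R15-17 spermatids and spermatozoa the list was the shortest of the spermatid lists. Intron 16 of Dpp6 (chromosome 4, 4060444 to 4060612), a subunit of neuronal potassium channels, rose from 16.3% to 63.4%, intron 1 of Nrp2 (chromosome 9, 69498866 to 69498939), a semaphorin receptor, from 0% to 45%, and exon 9 of the lamin gene Lmna from 47% to 74.1%. Intron 1 of Ncs1 (chromosome 3, 10588573 to 10588741), a neuronal calcium sensor, fell from 66% to 26.5%. Ttc23 and exon 23 of Rasgrf1, which had gained at the preceding step, fell to 13.7% and 68.2%. Gains numbered 1047 and losses 644, a gain share of 61.9% (Wilson 95% interval 59.6% to 64.2%), with gains from a median of 17.6% to 33.6% and losses from 74.1% to 55.0%. No list passed adjustment: synapse genes were listed at 8 of 68 members (odds ratio 3.13, Fisher exact test, adjusted p = 0.102, but 7.53 and 1.68e-04 over all annotated genes), stem cell genes and olfactory receptors at 3 of 28 and 3 of 64, and imprinted genes at 1 of 18. Spermatid, developmental, Wnt and chromatin lists held 2 members each, and the other lists none. Only 74.9% of the regions of this list carried an annotation, so genes and gene parts of the remaining regions are missing here. Gene parts did not differ between gains and losses past the threshold, with 65.1% of gains and 62.7% of losses between genes (Fisher exact test, adjusted p = 0.936).

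Regions listed in consecutive spermatid comparisons almost always went back in the opposite direction. From R1-8 through R9-12 to R13-14, 1628 pairs of regions gained and then lost methylation and 514 lost and then gained it, together 99.1% of 2161 overlapping pairs (Wilson 95% interval 98.6% to 99.4%). The share was 98.4% of 1342 pairs at the next step and 97.4% of 544 at the last. Consecutive comparisons share a stage, and simulated independent scatter of the stage means gave 99.8%, 99.6% and 99.9%. The observed shares of opposite direction are therefore no evidence of a reversal beyond chance. The overlap itself differed between the steps: 57.6% of the regions of the R1-8 to R9-12 list (Wilson 95% interval 56.0% to 59.2%) were in the next list, against 20.2% in the simulation. At the later steps the overlaps were 23.9% against 23.8% and 18.0% against 18.5%. The simulated scatter was set by the share of each list in the 60036 regions of any list, and not in all segments searched. It also left out the threshold on p and the bounds of a methylation level. The simulated overlaps follow from these choices, so the near equality at the later steps does not show overlap at chance level. The simulation holds no real differences, so the excess at the first step is not a measure of return. In regions present in both lists the net difference from R1-8 to R13-14 had a median of -0.9 points over 2139 regions, and 94.6% of them ended within 10 points of the start. The corresponding shares were 90.6% from R9-12 to R15-17 and 79.7% from R13-14 to spermatozoa. Independent scatter of the stage means, as simulated, gave 99.5%, 98.8% and 99.7% within 10 points. The simulated SDs were 3.79, 4.22 and 3.61 points, a setting that by itself keeps nearly all simulated net differences within 10 points. The observed shares are therefore no evidence of a return, and this simulation cannot exclude one.

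The authors' clusters of spermatid regions follow this course, and they too were selected on these levels. The clusters used here, numbered 3, 4, 7 and 8, held 2302, 1380, 1118 and 1701 regions, 68.8% of the 9449 regions in any spermatid list, and the medians below are over those with a level at the stage. Cluster 3 rose from a median of 4.9% at R1-8 to 16.7% at R9-12 and returned to 3.5% at R13-14, and of its 1209 regions in the first spermatid list 95.9% were gains. Cldn11 followed that course, while Smarca5 and Fzd1, also in cluster 3, fell at R9-12, and Slc38a2 rose only at R13-14. Cluster 4 went from 12.5% through 24.8% to 11.5%, and 89.9% of its 634 regions in the first spermatid list were gains. Spag16 and Robo1 followed it, while Ttc23 fell from 14.1% to 0% and Nrp2 from 15.6% to 1.8% at R9-12. Cluster 7, with Ece1, the endothelin-converting enzyme, at 97.2% and then 68.7%, fell from 96.8% to 84.6% at R9-12 and stood at 97.1% at R13-14. Cluster 8 fell later, from 97.1% at R9-12 to 84.7% at R13-14, and stood at 97.8% at R15-17, with losses in 99.0% of its 990 regions in the list from R9-12 to R13-14. Lzts2 followed that course. Dpp6, in the same cluster, went from 46.4% at R9-12 to 16.8% at R13-14 and stayed at 16.3% at R15-17. Promoters made up 13.6% and 11.2% of the genic regions of clusters 3 and 4 against 8.04% and 3.65% in clusters 7 and 8. In the authors' deposited table of terms, cluster 8 was led by synapse organization with 68 genes and an adjusted p of 7.00e-09, and cluster 3 by synaptic membrane with 4.99e-05, with synapse organization leading its biological processes at 0.00359 with 47 genes. In the authors' deposited table cluster 4 was led by second-messenger-mediated signaling with 30 genes and an adjusted p of 3.03e-04, and cluster 7 by positive regulation of cell projection organization with 38 genes and 5.36e-04.

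**Figure D3:**
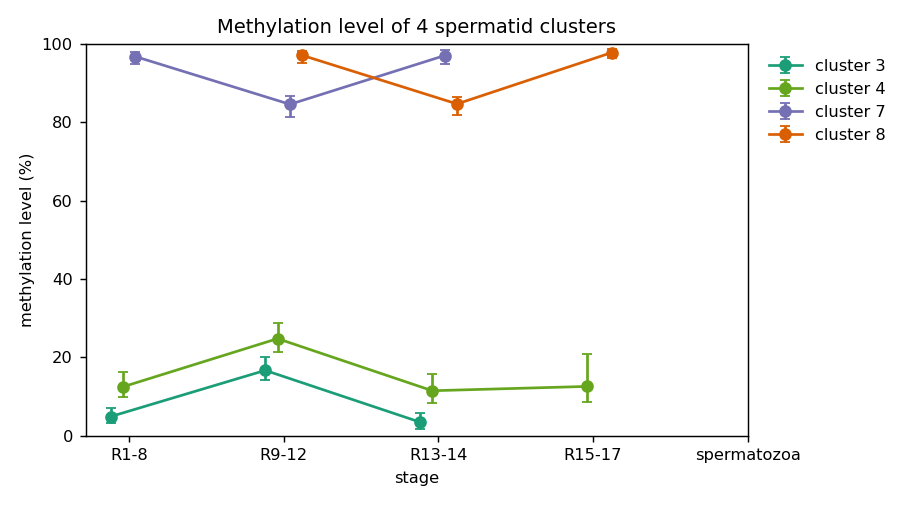
Median of the authors' mean methylation level in percent at each spermatid stage and in spermatozoa for the regions of clusters 3, 4, 7 and 8, over the regions with a level and with the interquartile range as error bars, drawn where at least 40% of a cluster's regions have a level. Clusters 3 and 4 reached 16.7% and 24.8% at R9-12, cluster 7 fell to 84.6% at R9-12, and cluster 8 fell to 84.7% at R13-14.

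The X chromosome held few of the regions that gained methylation in gonocytes. X-linked regions were 180 of 44477 from GD18 to GD20 (0.405%) and 293 of 46665 from GD20 to PND5 (0.628%), against 2.48% of the GD16 to GD18 losses and between 1.59% and 2.47% of the spermatid lists. From R1-8 to R9-12 gains were X-linked more often than losses, 3.10% against 1.21% (odds ratio 2.60, Fisher exact test, adjusted p = 5.99e-04 over 10 tests of X linkage). From R9-12 to R13-14 the gains were X-linked less often, 1.17% against 2.42% (odds ratio 0.479, Fisher exact test, adjusted p = 0.0155), as they were from R13-14 to R15-17, with 1.13% against 2.81% (odds ratio 0.396, adjusted p = 0.00443). The last step showed 2.58% against 1.86%, which did not pass the threshold (Fisher exact test, adjusted p = 0.507). At 30 points or more these lists held 1, 2, 3 and 2 X-linked regions, and the odds ratio from R9-12 to R13-14 turned to 3.31 with an unadjusted Fisher exact p of 0.416. Among the clusters, X linkage was more frequent in cluster 3 than in cluster 7 (3.65% against 0.894%, odds ratio 4.20, Fisher exact test, adjusted p = 3.11e-06) and in cluster 4 than in cluster 8 (2.46% against 0.647%, odds ratio 3.88, adjusted p = 7.48e-05).

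**Figure D4:**
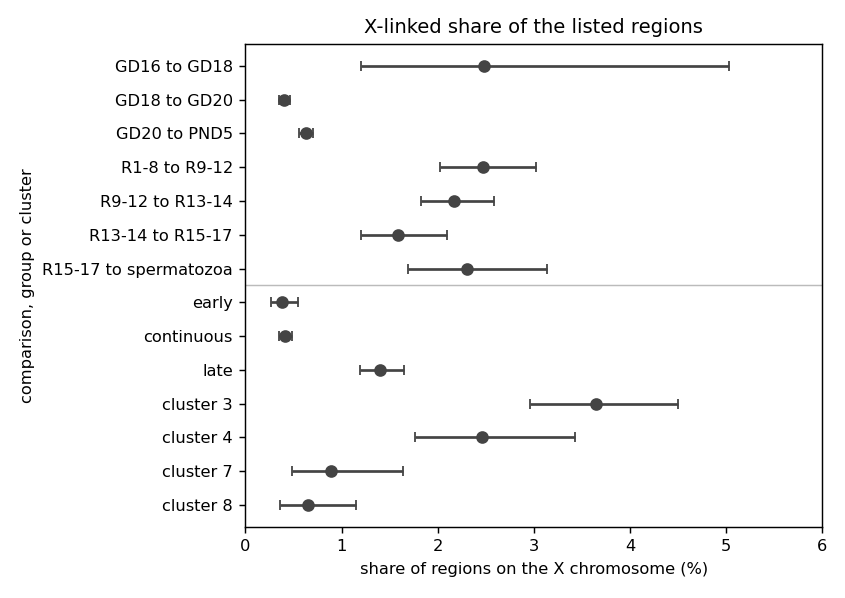
Points show the share of X-linked regions in percent in each of the 7 lists and in the authors' gain groups and clusters, with Wilson 95% intervals that cover counting error only. The share was 0.405% from GD18 to GD20 and 0.628% from GD20 to PND5, against 1.40% in the late gain group and 3.65% in cluster 3.

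The authors also named a small set of reprogrammed sites. All 17 genic regions of that set lay in introns, among them those of Nr1h2, Tcf3, Camta1, Nsd3, Fry, Pard6g, Unc119b, Aff1, Pdia5, Cxxc5, Sez6l, Ppp1r37, Kif13a, Skap1, Ppil1 and Ank1. They include the E protein gene Tcf3, the histone methyltransferase gene Nsd3 and the erythrocyte ankyrin gene Ank1. All of them were in a list used here, and the 14 with levels at both GD20 and PND5 rose from a median of 39.2% to a median of 94.3%. The intron region of Camta1, a transcription activator gene, went from 3.7% at GD18 through 57.3% at GD20 to 94.4% at PND5, and that of Sez6l from 11.8% at GD20 to 90.8% at PND5. Of the 28 intergenic regions of the set, 17 were in a list used here and 2 in the list from GD20 to PND5.

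In all 7 lists the strength of the authors' p-values followed the number of CpGs in a region. The authors' deposited table gives a median p of 2.95e-07 for regions of 5 CpGs and of 3.57e-26 for regions of 20 or more from GD18 to GD20. From R1-8 to R9-12 the authors' deposited table gives 0.00549 and 6.69e-07 for the same classes.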

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

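All comparisons of odds in this part except those within strata of CpG density, and the tests of an admixed cell population, of fewer X-linked segments and of a later gain on the X chromosome, were chosen only after the result was seen. The test within strata of CpG density was written before its own result. The direction of change differed between neighbouring spermatid comparisons. The odds of a gain from R1-8 to R9-12 were 8.18 times those from R9-12 to R13-14 (95% interval 7.44 to 8.99). Those from R9-12 to R13-14 were 0.0913 times those from R13-14 to R15-17 (0.0823 to 0.101), and those from R13-14 to R15-17 were 1.66 times those from R15-17 to spermatozoa (1.46 to 1.88, Fisher exact p = 6.56e-15). This last comparison depends on the threshold of the lists: the odds ratio turned to 0.60 with an adjusted p under 0.001 (57.0% against 68.9% gains, Fisher exact p = 0.00166), to 0.722 after adjustment over all 7 lists (61.1% against 68.6%, Fisher exact p = 0.00924) and to 0.754 at 30 points or more (53.1% against 60%, Fisher exact p = 0.422). Regions are not replicates, so these intervals do not cover spread between samples.

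The back-and-forth of spermatid levels, up for low regions such as Spag16 and Cldn11 at R9-12 and down for high ones such as Inha, was weighed against 2 technical explanations. Independent scatter of the stage means would give gains and losses alike in regions whose 2 levels average 35% to 65%, where no floor or ceiling favours a direction. In that band gains were 67.7% of 504 regions from R1-8 to R9-12, 24.4% of 664 from R9-12 to R13-14 and 59.0% of 478 from R13-14 to R15-17. This argues against independent scatter as the whole cause within the band. The band held only 504 of the 3722 regions from R1-8 to R9-12 and leaves out the low and high ones. It therefore cannot decide whether scatter accounts for the rise of low and the fall of high regions. An admixture in the R9-12 samples, of germ cells of other stages or of somatic cells that escaped the sort on germ-cell-specific fluorescence, may pull low and high regions towards the middle; 7.01% of regions (95% interval 6.24 to 7.88) would need an admixed share above 50%, while the median region would need 16.4%, and without a methylation profile of such cells this cannot be told apart from a change in the spermatids. Stage and any batch of preparation cannot be separated either, since no batch is given, and the biological difference between spermatid stages was not tested.

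The late gain group held more X-linked regions than the early and continuous groups together, with odds 3.50 times as high (95% interval 2.81 to 4.36, Fisher exact p = 3.80e-26). The ratio of the X shares, 3.46, restates this difference, so it decides nothing on fewer X-linked segments in the tables, and the number of segments searched on the X chromosome was not used here. Of the X-linked late regions 2.08% (95% interval 0.711 to 5.95) had reached 35% at GD20, against 1.29% of those on other chromosomes. No late region was in the list from GD18 to GD20, so low GD20 levels follow largely from the grouping. This share therefore cannot decide whether X-linked segments were missed at GD18. Within strata of CpG density the odds ratios were 3.96, 3.50 and 3.40, which argues against density. Among the regions that gained between GD20 and PND5, the median GD20 level on the X chromosome was lower by 14.1 points than on the autosomes (34.3% against 48.4%), but this largely restates the larger share of late regions on the X chromosome: within the late group the medians were 22.9% and 23.7% (permutation p of the means = 0.159) and within the continuous group 48.5% and 52.2% (permutation p of the means = 5.10e-04). A later gain on the X chromosome therefore stays open as a hypothesis that these values do not decide, as does read depth on the X chromosome, which is unknown.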

How the results depend on the processing

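The adjustment over the distinct regions of all 7 lists and the list tests with regions as the unit were chosen only after the data were seen. Over 74 results, 203 values were recomputed under alternatives: 122 kept their direction, side of the threshold or size, 67 moved, 9 kept their direction but lost the threshold, 0 gained it and 5 reversed. Counted among the 67 is a further change of direction, in the odds of X linkage in the comparison with spermatozoa. These odds had not passed the threshold as deposited. The directions of the fetal and neonatal lists held under every alternative run. Within each of these lists all regions but 4 at most go in 1 direction, so alternatives run on the same regions could hardly turn it. A limit of 30 points left these lists unchanged, as it is already their smallest difference. Such values are counted among the 122. No paired analysis was possible because the region lists hold means per stage and no values per sample. For the same reason the fit with a replicate block, the leaving out of single replicates and other coverage minimums were not run; the wider promoter, the midpoint rule, the stricter island rule and matched random lists were not run because no genome of the build was used. Depth limits every level to an unknown degree. Where no cause is named below, the cause was not tested.

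With an adjusted p under 0.001 the spermatid lists, in order of stage, held 1261, 1694, 277 and 424 regions, with gain shares of 72.2%, 16.8%, 57.0% and 68.9%. The median gains were then 15.2, 15.7, 22.4 and 15.05 points and the median losses -13.6, -15.5, -24.6 and -17.5 points. With at least 30 points they held 82, 153, 130 and 55 regions, fewer by construction, and the gain shares were 74.4%, 23.5%, 53.1% and 60%. Adjusted over the distinct regions of all 7 lists they held 1886, 2910, 561 and 582 regions, with gain shares of 71.2% from R1-8 to R9-12, 61.1% from R13-14 to R15-17 and 68.6% from R15-17 to spermatozoa. The odds of a gain from R13-14 to R15-17 against R15-17 to spermatozoa, 1.66 as deposited, reversed to 0.60, 0.754 and 0.722 under these 3 alternatives in turn, while the odds ratios between the earlier lists kept their direction and threshold. Weighted by length the gain share was 63.6% from R1-8 to R9-12 and 77.4% from R13-14 to R15-17.

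In regions of at least 200 bp the median difference was -32.05 points from GD16 to GD18 and 45.3 points from GD20 to PND5. In the spermatid lists such regions had median gains of 13.4, 13.5, 13.2 and 13.2 points and median losses of -12.7, -13.4, -15.8 and -13.2 points. Consecutive spermatid lists shared 32, 31 and 27 regions at 30 points or more, with opposite directions in 100%, 100% and 100% of them. Within 500 bp the opposite share was 98.3% from R1-8 to R13-14 and 97.1% from R9-12 to R15-17.

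At 30 points or more the X share was 1.22%, 1.31%, 2.31% and 3.64% in the spermatid lists, from 1, 2, 3 and 2 regions. The odds ratio of X linkage, gains against losses, reversed to 3.31 (Fisher exact test, p = 0.416) from R9-12 to R13-14 and was 0.434 (Fisher exact test, p = 0.60) from R13-14 to R15-17. From R15-17 to spermatozoa it turned as well, from 1.39 as deposited, which had not passed the threshold, to 0.656 (Fisher exact test, p = 1). It had no finite value from R1-8 to R9-12.

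Of the list tests, 5 passed as reported, 19 against all annotated genes, 2 at 30 points or more and 3 with regions as the unit. Among the 19, synapse genes were listed more often in all 7 comparisons (odds ratios 5.68 to 11.3). Olfactory and vomeronasal receptors were listed less often in all 7 (odds ratios 0 to 0.120). The rest were listed more often: Wnt and TGF-beta genes from GD18 to GD20 and from GD20 to PND5, stem cell genes from GD20 to PND5, and spermatid genes and developmental transcription factors from R9-12 to R13-14. The 3 with regions as the unit were developmental transcription factors, Sertoli cell markers and olfactory receptors, all with fewer listed gains from GD18 to GD20. List tests that did not pass as reported are not among the results counted above. Against all annotated genes the odds ratio of developmental transcription factors was 0.592 (adjusted p = 0.148) from GD18 to GD20 and 0.762 (adjusted p = 0.587) from GD20 to PND5 (Fisher exact tests), and with regions as the unit the latter was 0.915 (adjusted p = 1). For synapse genes with regions as the unit the odds ratios were 1.21 (adjusted p = 0.780), 1.04 (adjusted p = 1) and 1.39 (adjusted p = 0.544) in the first spermatid comparisons (Fisher exact tests). At 30 points or more they were 7.77 (adjusted p = 0.898) and 9.78 (adjusted p = 0.399), and from R13-14 to R15-17 the odds ratio reversed to 0 (Fisher exact test, adjusted p = 1) with no listed member. In the authors' deposited table of terms, an adjusted p under 0.01 left 74 terms for the early, 116 for the continuous and 78 for the late group, 11 for stable and 39 for dynamic segments, and 37, 14, 20 and 60 for clusters 3, 4, 7 and 8.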

Other observations

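The tests of direction in regions shared by fetal and spermatid lists, overall and within bands of the earlier level, were chosen only after the counts were seen, while those on segments per gene and on CpG density at GD16 were written before their results. Of the 44477 regions that gained methylation between GD18 and GD20, 5.09% were listed again in spermatids, with 633, 1280, 1131 and 169 regions in the spermatid lists in order of stage, and the share of gains among them differed from that among the other spermatid regions at each step. The exon region of Gopc, an acrosome gene, rose from 7.4% at GD18 to 72.4% at GD20 and stood at 98.2%, 83.2% and 98.3% at R9-12, R13-14 and R15-17. An intron region of Ddx25, an RNA helicase gene of spermatids, rose from 4.4% to 69.6% by GD20 and went from 97.3% to 86.2% and 96.7% between R1-8 and R13-14. Of 633 regions shared by the GD18 to GD20 gains and the R1-8 to R9-12 list, 90.5% lost methylation in the spermatids, against 21.5% of the other 3089 (odds ratio of a gain 0.0286, Fisher exact test, adjusted p = 9.13e-245 over 12 tests). From R13-14 to R15-17 the shared regions gained in 93.8% of 1131 cases against 60.5% of the others (odds ratio 9.91, Fisher exact test, adjusted p = 2.49e-102). From R9-12 to R13-14 losses were the majority in both sets but less frequent in the shared regions (64.0% against 85.1%, Fisher exact test, adjusted p = 5.67e-56), and from R15-17 to spermatozoa 59.2% of the shared regions and 35.7% of the others were losses (Fisher exact test, adjusted p = 8.13e-09). The sets start from different levels, and within bands of the earlier level (under 20%, 20% to 80%, and above, 24 tests with those of the next paragraph) the difference from R1-8 to R9-12 did not pass adjustment. In the upper band 96.7% of shared and 93.1% of other regions were losses there (Fisher exact test, adjusted p = 0.0550). From R9-12 to R13-14 it passed in the middle band, with gains in 78.0% of 127 shared and 16.1% of other regions (Fisher exact test, adjusted p = 1.30e-48), but not in the upper band, with losses in 68.5% and 74.4% (Fisher exact test, adjusted p = 0.0550). From R13-14 to R15-17 it passed in both, and in the upper band gains were 94.1% of 977 shared and 57.6% of 330 other regions (adjusted p = 1.30e-48 by Fisher exact test). From R15-17 to spermatozoa the difference within the middle and upper bands was opposite to that over all levels, with losses in 75.4% of shared and 92.2% of other regions of the upper band (Fisher exact test, adjusted p = 2.16e-04). Regions are not replicates.

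Of the 282 regions that had lost methylation by GD18, 88 (31.2%, Wilson 95% interval 26.1% to 36.8%) were listed again in spermatids. They included the Cfi promoter, which stood at 6.7%, 23.3%, 19% and 6% from R1-8 to R15-17, and intron 3 of Robo1, which went from 2.2% through 39% to 9.9%. Of the 39 such regions in the list from R1-8 to R9-12, 37 gained (94.9% against 66.5% of the others, Fisher exact test, adjusted p = 6.08e-05), and 58 of 61 lost methylation from R9-12 to R13-14 (95.1% against 80.1%, adjusted p = 0.00212). No band of the earlier level passed adjustment at either step. From R1-8 to R9-12, 30 of the 39 regions started under 20%, where 97.4% of the other regions gained too. From R9-12 to R13-14 losses were 100% of 20 shared regions against 90.8% under 20% (Fisher exact test, adjusted p = 0.457) and 97.1% of 34 against 80.7% in the middle band (odds ratio of a gain 0.126 against 0.208 over all levels, Fisher exact test, adjusted p = 0.0538). The odds ratio in the middle band rests on 1 gain among the 34 shared regions. In the upper band losses were 71.4% of 7 shared regions against 70.3% of the others. With so few regions the bands cannot decide whether the difference holds at like starting levels. At the later steps the shared regions did not pass adjustment, with 8 gains and 8 losses from R13-14 to R15-17 (Fisher exact test, adjusted p = 0.0529) and 66.7% gains among 24 regions from R15-17 to spermatozoa against 61.8% (Fisher exact test, adjusted p = 0.679). Of the 282 regions erased by GD18, 164 (58.2%, Wilson 95% interval 52.3% to 63.8%) were listed as gains by PND5, Etv5 with 59.5% at GD20 and 98.4% at PND5 and Tie1 with 30.9% and 95.7%, and 118 were not. The regions without a listed gain had 4.55 CpGs per 100 bp against 3.47, a difference of medians of 1.08 and of means of 1.10 (permutation test of the means, p = 9.90e-04), and 25.4% of them against 43.9% were genic. In 1182 regions with a level in both PND5 spermatogonia and R1-8 spermatids, the medians were 89.7% and 91.8%, and 128 regions were higher at R1-8 by more than 10 points and 194 lower.

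Synapse and axon guidance genes were listed more often than other genes in the first spermatid comparisons, and a candidate explanation is more listed segments per gene. Genes of that list had a median of 7 annotated segments against 2 in other genes. Counted over segments, the odds ratio lay near 1, within bounds set beforehand, in 5 of 7 comparisons, but only 2 of these 5 were among the 3 comparisons with an excess by genes. From R1-8 to R9-12 and from R9-12 to R13-14 it was 1.21 and 1.04 against 3.59 and 3.66 by genes, and from R13-14 to R15-17 it lay outside the bounds at 1.39 against 4.20 (Fisher exact test over segments, p = 0.0741, adjusted p = 0.544). The highest over segments was 1.88, from GD16 to GD18. The annotated segments are only those that the authors had listed or grouped at some step, so their number per gene is part of the outcome. The odds ratio over segments asks only at which step such a segment was listed. It therefore cannot decide whether more searched segments per gene account for the excess at any step. A difference in the genes themselves stays open too.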
